A study of Escherichia coli str. K-12 substr. MG1655 with 4 samples.

How the data were processed

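Total RNA from Escherichia coli K-12 MG1655 was sequenced in 4 libraries, 2 from the wild type (WT) and 2 from a strain whose ribosomal protein S1 lacks its last 2 C-terminal OB-fold domains (rpsAΔ56). Per the labels' protocols, cells grew in LB at 37 °C to an optical density of 0.4, ribosomal RNA was depleted, and adapters were ligated to both ends of sonicated RNA before cDNA of 200 to 500 bp was made. Per the labels, replicate 1 of each strain was read single-end at 50 nt and replicate 2 paired-end at 75 nt, and both are named biological replicates. Replicate number and sequencing mode therefore cannot be separated within a strain.

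Trimmomatic, Bowtie2, HTSeq and DESeq2 are named in the submitters' processing notes, and their versions, the genome build and the strand setting of the counting are not given in the sources used here. Without a stated strand setting, reads of a gene and of an antisense or overlapping partner cannot be told apart, and near-identical copies (pinR and pinQ, ynaE and ydfK, the ibs genes, the 5S rRNA genes) may share reads. The authors deposited 1 table of 4451 genes. It holds raw read counts per gene and library, per the file headers and the whole-number values, and these were the input of every test. The 4 normalized columns in the deposited table, treated here as a score because the values are rounded, equalled the counts times 1 factor per library. Those factors were 1.31 and 0.840 for WT and 1.01 and 0.878 for rpsAΔ56, and the values lay within 1 of the product for all 4451 genes in 3 libraries and for 4450 in rpsAΔ56 replicate 2. The authors' table also gives a log2 fold change, a linear fold change as a ratio, and a p-value and adjusted p-value for rpsAΔ56 against WT, per the file headers. These are described as the authors' values and entered no test.

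The gene symbols of the deposited table were used as names. Its identifier and protein accession columns were not used, because 157 protein-coding genes carry an RNA identifier and 156 of the 173 RNA genes carry a coding-sequence identifier. RNA genes were therefore told by the gene type in the RefSeq name table of assembly ASM584v2, a choice made after seeing the data. Of the 4451 symbols, 4226 matched that table exactly, 213 matched a synonym and 12 matched none. The name table also gave which genes neighbour each other, and no coordinates are reported because no build is named.

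Library totals were 23006218 and 25682239 counts for WT replicates 1 and 2, and 28145166 and 25763214 for rpsAΔ56. A count of 0 in these libraries allows up to 3 counts, between 0.0979 and 0.150 CPM. Counts of replicates differed far beyond sampling noise, with a chi-square per degree of freedom of 1384 in WT and 1998 in rpsAΔ56, so the replicates were kept as separate samples.

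The comparison used edgeR 4.0.16 with limma 3.58.1 in R 4.3.3. The filterByExpr filter left 4392 genes, TMM factors scaled the libraries, and the quasi-likelihood test compared 2 rpsAΔ56 with 2 WT libraries without covariates. P-values were adjusted by Benjamini-Hochberg with a threshold of 0.05. Standard errors (SE) of log2 fold changes were derived from the quasi-likelihood F statistic. CPM are counts scaled by TMM-adjusted library sizes, and fold changes within a same-numbered pair use log2(CPM + 1) and have no test. Because the replicate number marks the sequencing mode in the labels, it pairs the samples. The deviations of same-numbered samples from their group means correlated across genes at Pearson r = 0.472 (Spearman 0.445), with genes not being independent replicates. A fit with the replicate number as a block was therefore made beside the main one, and its common dispersion was 0.159 against 0.285.

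Before the data were examined, 31 gene lists, the tests, the alternatives and the naming rule were fixed. Of 1067 list entries, 1058 matched a gene of the table. Lists were tested with camera at a preset correlation of 0.01, again with an estimated correlation, and with fry, and were adjusted over the 31 lists. Named genes were rpsA; the 10 largest rises and 10 largest falls among calls with a mean count of at least 50 and the same direction in both pairs (all of them if fewer); up to 3 called members per list with the lowest adjusted p; the 5 largest rises and falls among calls of the blocked fit; and up to 4 members with the lowest unadjusted p in each list past the threshold in camera. This gave 63 genes, and a gene outside the rule is said to have been chosen after its values were seen. Shares of counts carry 95% Wilson intervals, which cover counting error only, and were compared by an exact permutation test, two-sided, that cannot go below 0.33 with 2 libraries against 2. Some tests of technical explanations were dropped or replaced after their values were seen, since their outcome could not decide between explanations; these concerned the srl operon, the small regulatory RNAs and library composition.

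Alternatives were the replicate block, RLE and upper-quartile scaling, no filter, a mean count of at least 50, DESeq2 1.42.0 with and without the block, limma-voom, protein-coding genes alone, counts thinned to the smallest library, each library left out, an adjusted p under 0.01, and a minimum of 2-fold. Corrections for GC content and gene length were planned and not run, because no genome sequence was used here and the build is not named.

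The scripts were tested on simulated counts with 200 changed genes, drawn for this comparison from the means and dispersions of these libraries over 4392 genes. The edgeR fit without block ran on 4370 of them and recovered 0 of 50 genes changed 2-fold, 0 of 50 changed 4-fold, 24 of 50 changed 16-fold and 47 of 50 changed 64-fold, with 0 calls of unchanged genes. With the block, the recovered numbers were 0, 5, 50 and 50, with 1 call of an unchanged gene. DESeq2 without block recovered 0, 5, 48 and 50 with 1 such call, and with the block 2, 32, 50 and 48 with 13 such calls. A simulated list of 30 genes shifted by 1 log2 unit had an adjusted p of 2.19e-15 in camera with the preset correlation and 0.337 with the estimated one. Of 30 unshifted lists, 0 was called by either. The simulated genes were drawn independently, whereas estimated correlations in the real lists reached 0.473 (sulfur assimilation). The simulation therefore does not show how often the preset correlation calls unshifted lists of correlated genes.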

Results

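Ribosomal protein S1, encoded by rpsA, binds messenger RNA on the small ribosomal subunit and helps it enter the ribosome. The series asked how the transcriptome of Escherichia coli MG1655 differs when the last 2 OB-fold domains of S1 are removed (rpsAΔ56). Total RNA was sequenced from exponentially growing cultures, in 2 biological replicates of the wild type (WT) and 2 of the mutant. Library totals lay between 23006218 and 28145166 counts over 4451 genes. Replicate 1 of each strain was sequenced single-end and replicate 2 paired-end, so values are also given within each same-numbered pair.

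The mutated gene itself had lower counts in both mutant libraries than in both WT libraries. rpsA had 12620 ± 435 CPM in WT and 3376 ± 519 CPM in rpsAΔ56 (mean ± SD, n = 2 each), from raw counts of 245440 and 396077 in WT and 94525 and 83582 in the mutant. Its log2 fold change was -1.90 (SE 0.696), with -1.72 in the single-end pair and -2.10 in the paired-end pair. The change did not pass the edgeR quasi-likelihood test (adjusted p = 0.424, and 0.205 with the replicate block), and it passed in DESeq2 (log2 fold change -1.95, adjusted p = 0.0440). In the authors' deposited table rpsA stood at -1.76 with an adjusted p of 0.00641. Reads from the retained part of the gene still count, while the removed part can give none in the mutant. The gene-level fall therefore mixes missing sequence with any change in transcript level, and the 2 were not separated.

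Of the 19 genes called by edgeR in rpsAΔ56, 13 were members of the flagella and chemotaxis list and 6 lay outside it. The chemoreceptor genes tap, tar and tsr and the chemotaxis signalling genes cheA, cheW, cheB and cheY fell by 6.52 to 7.28 on the log2 scale. Outside the flagella list, yhjH (a cyclic-di-GMP phosphodiesterase gene), flxA, ves and flu (antigen 43, an autotransporter adhesin) also fell, and srlA, a sorbitol transporter gene, was the only gene that rose in that fit. In the edgeR fit 19 of 4392 genes passed an adjusted p of 0.05, 18 lower and 1 higher, and 448 had an unadjusted p under 0.05.

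tap had the lowest log2 fold change, -7.28 (SE 0.735, adjusted p = 0.0170), with 348 ± 78.5 CPM in WT and 2.23 ± 0.0429 CPM in the mutant (SD, n = 2 each, edgeR). yhjH stood at -7.14 (SE 0.725), tar at -6.87 (SE 0.753), cheB at -6.65 (SE 0.748), cheW at -6.56 (SE 0.696) and cheA at -6.52 (SE 0.702), each with an edgeR adjusted p of 0.0170. cheY stood at -6.84 (SE 0.864, edgeR adjusted p = 0.0212) and tsr at -6.78 (SE 0.936, edgeR adjusted p = 0.0320). ves stood at -6.29 (SE 0.753), flxA at -6.24 (SE 0.756) and flu at -5.90 (SE 0.705), with edgeR adjusted p of 0.0170, 0.0171 and 0.0170. All 11 of these genes were lower in the mutant in both pairs. With the replicate block 18 genes were called, 17 of them shared with the 19, and cheY (adjusted p = 0.0671) and fliS (adjusted p = 0.0758) were not among them. The block added fliC, the flagellin gene (log2 fold change -6.46, edgeR adjusted p = 0.0282 with the block against 0.126 without), which was looked at after its values were seen. The number of calls depended on the libraries and the tool: it was 43 without WT replicate 1, 56 without rpsAΔ56 replicate 1, 32 without rpsAΔ56 replicate 2, 177 in DESeq2 (84 higher, 93 lower), 361 in DESeq2 with the block (189 higher, 172 lower), and 0 at an adjusted p under 0.01 in edgeR. The 12 named genes that were called stayed called with each library left out in turn.

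**Figure D1:**
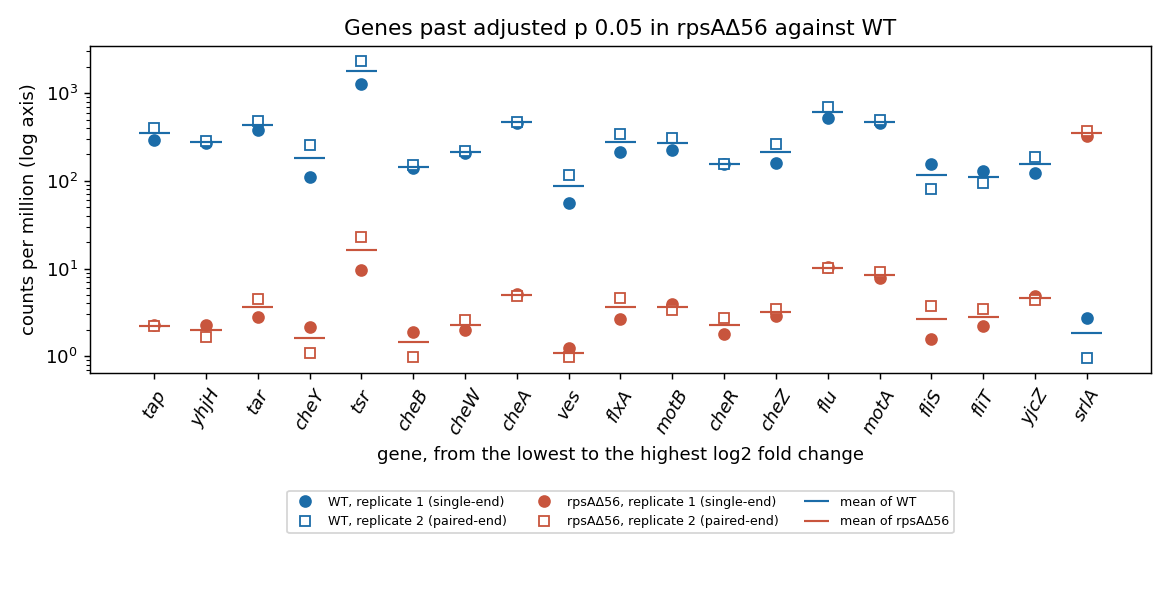
CPM (log axis) of the 19 genes past an adjusted p of 0.05 in edgeR, with 1 point per library and a line at each group's mean. The WT points lie above the rpsAΔ56 points for 18 genes, and below them for srlA.

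Almost the whole flagella and chemotaxis list lay lower in rpsAΔ56. Of 53 measured genes, 52 had a negative log2 fold change and 51 were lower in both pairs, with a median of -3.37 over the list, a 10.3-fold lower level. The median was -4.15 in the single-end pair and -2.55 in the paired-end pair. Over all genes tested 13 members fell, and 48 fell when p was adjusted over the list alone. The 5 members that did not pass were fliE, fliZ, flgA, trg and flhD, named after their values were seen. flhD, which with flhC encodes the master regulator of flagellar genes, had the only positive log2 fold change of the list, 1.56 (SE 0.997, edgeR adjusted p = 0.601), with -0.14 in the single-end pair and 4.20 in the paired-end pair. The list as a whole passed camera with the preset correlation (adjusted p = 1.12e-85) but not with an estimated correlation (adjusted p = 0.36). By the authors' deposited values, 50 of the 53 were lower and 0 higher at an adjusted p under 0.05. The list took 2.85 ± 0.336% of all counts in WT and 0.204 ± 0.136% in the mutant (SD, n = 2 each; exact permutation p = 0.33, the smallest this design allows).

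The rise of srlA was large and appeared in both pairs. srlA encodes a subunit of the sorbitol phosphotransferase transporter, and its raw counts were 54 and 29 in WT against 8245 and 10362 in rpsAΔ56, a log2 fold change of 7.59 (SE 0.884, edgeR adjusted p = 0.0170). The downstream genes srlE (5.36, SE 1.03, edgeR adjusted p = 0.126) and srlD (4.85, SE 1.10, edgeR adjusted p = 0.222) did not pass, and both passed in the authors' deposited table (adjusted p = 3.84e-13 and 6.55e-06). The other genes of the operon, looked at after their values were seen, did not pass in edgeR either: srlB stood at 5.42 (SE 1.51; called in the authors' table, adjusted p = 2.02e-08), srlM at 2.26 (SE 1.10), srlR at 0.69 (SE 0.706) and srlQ at -0.18 (SE 0.571). Without rpsAΔ56 replicate 1, srlE and srlD were called in edgeR as well (adjusted p = 0.00407 and 0.00659). Genes next to the operon, chosen after the values were seen, had log2 fold changes between -0.69 (pncC) and 0.44 (norW), none past the threshold.

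**Figure D2:**
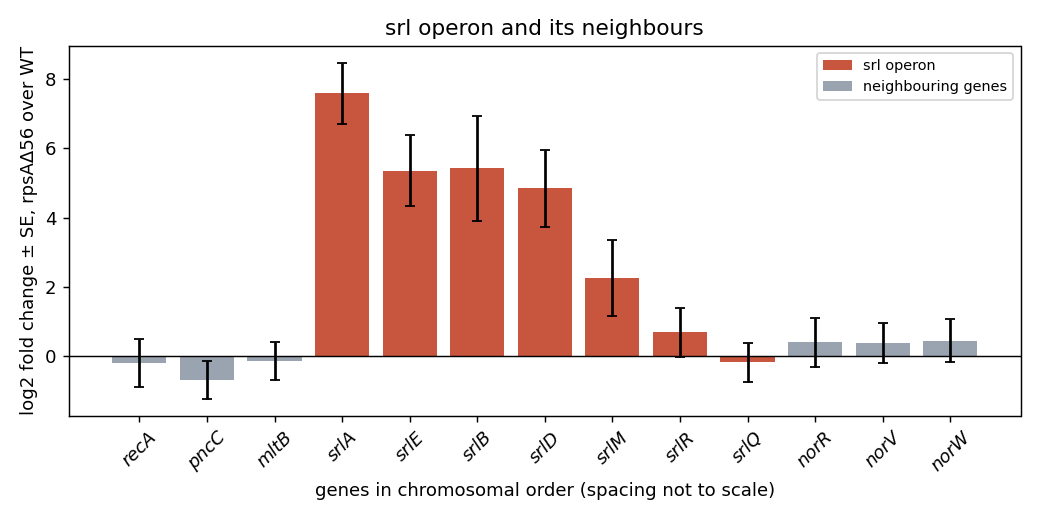
Log2 fold change of rpsAΔ56 over WT with its SE (edgeR, 2 libraries per group) for the srl genes and the nearest 3 measured genes on each side, in chromosomal order. srlA, the only one past the threshold, is highest at 7.59, srlQ is lowest of the operon at -0.18, and the 6 neighbours lie between -0.69 and 0.44.

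Among the other lists fixed before the data were examined, genes for nucleotide synthesis and for charging transfer RNA lay lower in rpsAΔ56, and genes for small regulatory RNAs and for the use of other carbon sources lay higher. All 29 purine and pyrimidine biosynthesis genes had negative log2 fold changes (median -1.32, camera adjusted p = 2.16e-10), and 28 were lower in both pairs. The examples with the lowest p were pyrB, the catalytic subunit gene of aspartate transcarbamoylase (-2.38, SE 0.574), guaA (-2.50, SE 0.673), the uracil permease gene uraA (-2.07, SE 0.558) and codA (-1.75, SE 0.569), none past the edgeR threshold alone. All 23 aminoacyl-tRNA synthetase genes were negative as well (median -0.85, camera adjusted p = 1.94e-05), led by serS (-1.82, SE 0.580), tyrS (-1.90, SE 0.636), glyQ (-1.99, SE 0.713) and glyS (-1.40, SE 0.646). With an estimated correlation, the adjusted p of these lists was 0.36 and 0.563. By the authors' deposited adjusted p, 6 and 3 of their members were lower and 0 higher.

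Of 39 small regulatory RNAs, 36 had a positive log2 fold change (median 1.93, camera adjusted p = 6.70e-11), although the median was 0.34 in the single-end pair and 2.85 in the paired-end pair, and it was 1.01 without rpsAΔ56 replicate 2 and 3.03 without WT replicate 1. micA (3.68, SE 0.911), ryeA (3.32, SE 0.857), the iron-responsive ryhB (3.09, SE 0.948; 2.25 and 4.90 in the single-end and paired-end pairs, and 5.07 without WT replicate 1) and sibB (2.55, SE 0.681) had the lowest p, and none passed edgeR alone. The authors' deposited table lists 18 of these RNAs as higher and 0 as lower. Among 98 genes for alternative carbon source uptake and catabolism, 83 were positive (median 1.06, camera adjusted p = 7.27e-10), with srlA called and lldP, a lactate permease gene, at 3.28 (SE 0.714). There the authors' table has 29 higher and 3 lower. With an estimated correlation both lists had an adjusted p of 0.563.

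Lists with smaller shifts followed. Heat shock genes lay lower (median -0.74 over 22 genes, camera adjusted p = 0.00455), among them the chaperone genes dnaJ (-1.83, SE 0.588) and groL (-1.95, SE 0.707) and the protease genes hslU (-1.76, SE 0.583) and hslV (-1.75, SE 0.604). Nucleoid and DNA topology genes lay lower too (median -0.55 over 16 genes, camera adjusted p = 0.0253), with stpA at -2.80 (SE 0.763), topA at -0.99 (SE 0.642) and gyrA at -0.89 (SE 0.686). The value of hupB (-2.07, SE 1.28) rested on WT replicate 2 and was 0.77 without it. Protein secretion genes had a median of -0.76 over 19 genes (camera adjusted p = 0.0479), with secF at -1.51 (SE 0.607), ffh at -1.30 (SE 0.629), secE at -1.29 (SE 0.641) and ftsY at -1.23 (SE 0.645). The list of type 1 fimbriae and antigen 43 passed in the lower direction (median -0.35 over 10 genes, camera adjusted p = 0.0191), and its called member was flu, while fimI (-2.04, SE 0.772), fimA (-1.18, SE 0.544) and fimC (-0.54, SE 0.60) did not pass. These 4 lists each had an adjusted p of 0.563 with an estimated correlation.

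Cold shock genes lay higher (median 1.00 over 16 genes, camera adjusted p = 0.0253, and 0.566 with an estimated correlation), with 9 of 16 positive, 7 negative and 8 higher in both pairs. Adjusted over the list alone, 4 of them rose and none fell: cspI (4.14, SE 0.650), cspB (2.71, SE 0.760), and the prophage genes ynaE (3.63, SE 0.770) and ydfK (3.58, SE 0.920), which are near-identical copies. The cold shock median was -0.37 without rpsAΔ56 replicate 1. Iron acquisition genes lay higher (median 0.76 over 48 genes, camera adjusted p = 0.00952). They were led by nrdH (3.91, SE 1.05), nrdI (2.47, SE 0.559) and nrdE (2.45, SE 0.598) of an alternative ribonucleotide reductase. The ferric citrate transport gene fecB stood at -2.17 (SE 0.668). By the authors' deposited adjusted p, 7 members of the list were higher and 5 lower. The higher ones were the ribonucleotide reductase genes nrdH, nrdI, nrdE and nrdF, and fhuE, fepB and entD. The lower ones were fecA, fecB, fecC, fecD and fecE. The shift of the list is therefore not a shared rise of genes for iron uptake. Toxin-antitoxin genes (median 0.58 over 39 genes, camera adjusted p = 0.0253) were led by tisB (3.12, SE 0.919) and hicB (1.88, SE 0.841). ibsA (2.77, SE 1.21) and ibsD (2.74, SE 1.27), which may share reads with near-identical copies, were -0.71 and -0.25 without rpsAΔ56 replicate 2. Cryptic prophage genes (median 0.47 over 49 genes, camera adjusted p = 0.0492) included pinR (3.11, SE 1.03) and pinQ (3.03, SE 1.01), torI (2.24, SE 0.918) and xisE (1.58, SE 0.678). Housekeeping and ribosomal RNAs had a median of 0.28 over 26 genes (camera adjusted p = 0.0253), led by the 5S rRNA copies rrfG (2.25, SE 0.712), rrfD (2.39, SE 0.773), rrfB (2.42, SE 0.915) and rrfH (1.44, SE 0.599). These 4 copies had only 5 to 48 counts per WT library. Of the 26 genes 22 are ribosomal RNA copies, which camera at the preset correlation treats as nearly independent. Ribosomal RNA as a whole did not rise, with mean shares of counts of 0.562% in WT and 0.549% in rpsAΔ56. With an estimated correlation the adjusted p was 0.563 for the other 4 lists.

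**Figure D3:**
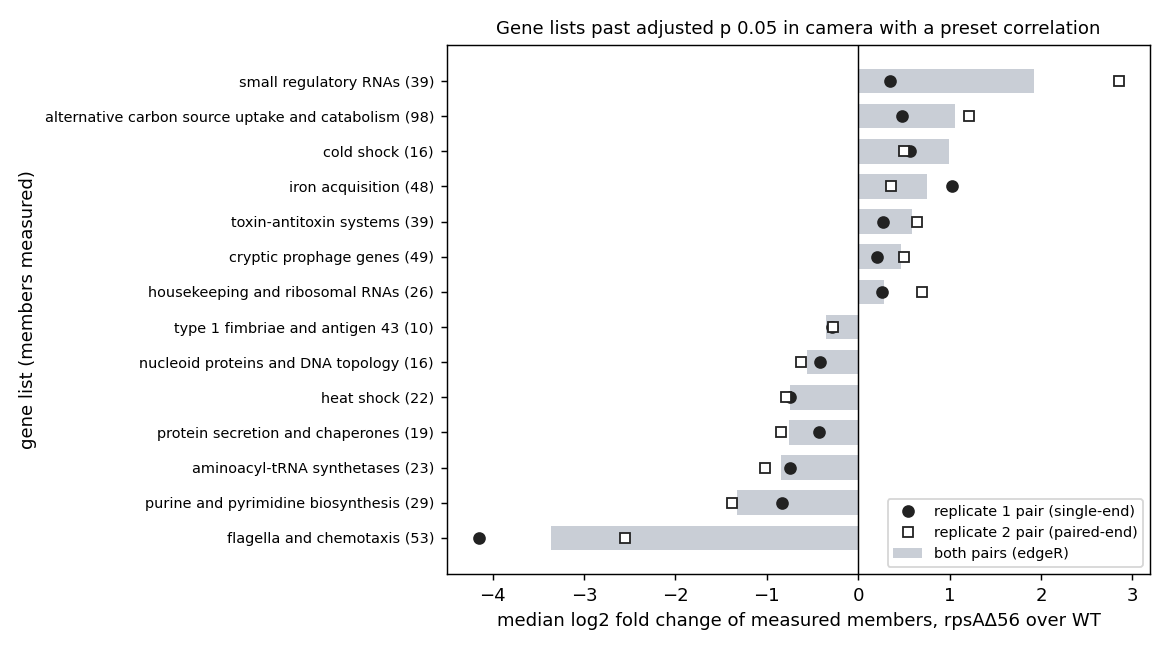
Median log2 fold change of rpsAΔ56 over WT for the 14 gene lists past an adjusted p of 0.05 in camera with the preset correlation, as bars for the edgeR fit and as points for each same-numbered pair. The flagella list lies lowest at -3.37, and the small regulatory RNA list has points at 0.34 and 2.85.

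In all, 14 of 31 lists passed, 7 higher and 7 lower, and 0 passed with an estimated correlation or in fry. In the simulation, the estimated correlation also missed the list shifted by 1 log2 unit (camera adjusted p = 0.337). Not passing with it therefore does not show that a list is unshifted. With each library left out in turn 5 of the 14 stayed past the threshold, those for flagella, small regulatory RNAs, nucleotide synthesis, carbon sources and aminoacyl-tRNA synthetases. The number of lists was 7 without WT replicate 1 and 9 without rpsAΔ56 replicate 2. Under other settings it lay between 11 (protein-coding genes alone, and DESeq2) and 16 (replicate block, and limma-voom). The cryptic prophage list lost the threshold with upper-quartile scaling, no filter, thinned counts and DESeq2 (adjusted p 0.0503 to 0.0599), and protein secretion with a mean count of at least 50, protein-coding genes alone, thinned counts and DESeq2 (0.0504 to 0.0756). Toxin-antitoxin genes lost it with a mean count of at least 50 (0.0570), housekeeping RNAs in DESeq2 (0.0665) and cold shock in limma-voom (0.0778). Single members that missed the edgeR threshold passed it with a library left out: 8 without rpsAΔ56 replicate 1 (cspI, nrdH, srlE, lldP, srlD, ryeA, tisB and ibsA; adjusted p 0.00407 to 0.0485), 5 without rpsAΔ56 replicate 2 (cspI, ynaE, ydfK, pinR and pinQ; 0.0368 to 0.0484), 2 without WT replicate 1 (micA and ryhB; 0.0358 and 0.0472) and 1 without WT replicate 2 (cspI; 0.0437).

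The genes closest to the mutated protein did not shift as a group past the threshold. The 53 genes of the ribosomal protein list, which leaves out rpsA, had a median of -0.32 (camera adjusted p = 0.151). Of these, 0 were called by edgeR or in the authors' deposited table. In the ribosome assembly and hibernation list, edgeR called 0 of 19 genes. By the authors' deposited adjusted p, 2 of its members were higher and 0 lower. The higher ones were rmf and raiA, looked at after their values were seen. Both stood at a deposited log2 fold change of 2.23 (adjusted p = 0.00109 and 0.00124). Translation factors (-0.64, 0.0655) and RNA polymerase and transcription factors (-0.55, 0.0536) did not pass, but did with the replicate block, at camera adjusted p of 0.0463 and 0.0475, and not with an estimated correlation there (adjusted p = 0.636 each). Median and camera adjusted p were -0.52 and 0.0775 for RNA decay and processing, -0.41 and 0.432 for ribosome assembly and hibernation, and 0.47 and 0.0775 for the general stress regulon. They were 0.24 and 0.0808 for envelope stress, 0.39 and 0.289 for acid resistance, 0.19 and 0.378 for the SOS response, -0.16 and 0.495 for oxidative stress, and 0.27 and 0.437 for curli and biofilm. For metabolism they were 0.32 and 0.178 for sulfur assimilation, 0.35 and 0.360 for amino acid biosynthesis, -0.17 and 0.229 for anaerobic respiration, and 0.02 and 0.533 for the TCA cycle list. In that last list aceB (4.11, SE 0.669) and aceA (3.43, SE 0.622) of the glyoxylate shunt, named after their values were seen, rose when adjusted over the list alone, and neither passed over all genes (edgeR adjusted p = 0.0730 and 0.110). For the envelope they were 0.36 and 0.437 for porins and lipoproteins, and 0.13 and 0.759 for lipopolysaccharide and other surface polysaccharides, where camera's direction was lower despite the positive median. The authors' deposited adjusted p calls 6 envelope stress genes higher and 0 lower. For the TCA cycle list these numbers were 5 and 0, and for porins and lipoproteins 3 and 1. Amino acid biosynthesis and anaerobic respiration each had 1 higher and 2 lower.

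The authors' deposited table calls more genes from the same counts. At an adjusted p under 0.05 it has 352 genes, 182 higher and 170 lower in rpsAΔ56, among 3775 with an adjusted p. It includes all 19 genes called here by edgeR, each in the same direction. By its log2 fold changes tap stood at -6.48, yhjH at -6.36, flu at -5.29 and srlA at 6.56. DESeq2 run here on the same counts called 177 genes, 175 of them shared with the table, and with the replicate block 361, 339 shared. The formula behind the deposited values is not given in the sources used here. A DESeq2 fit with the block and a fold-change prior, added after seeing the data, came closest, with a median absolute log2 difference of 0.00593 and 342 calls, 335 shared.

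Sequencing mode was compared across both strains as a measure of the technical split. In edgeR 0 of 4392 genes passed an adjusted p of 0.05 for paired-end against single-end libraries with genotype as a covariate, with 780 genes at an unadjusted p under 0.05, against 727 for genotype with the replicate block. Without the covariate 0 genes passed and 473 were under that value, against 448 for genotype without the block. No other tool was run for this comparison.

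One small RNA, gcvB, chosen after its values were seen, took a larger share of counts in both mutant libraries than in both WT libraries. This RNA, which represses amino acid and peptide transport genes, took 3.93% (95% Wilson interval 3.92 to 3.94) and 2.39% (2.38 to 2.40) of counts in WT replicates 1 and 2, and 8.86% (8.85 to 8.87) and 25.5% (25.5 to 25.5) in the mutant. All RNA genes together held 12.2 ± 2.73% in WT and 26.4 ± 12.5% in rpsAΔ56 (SD, n = 2 each; exact permutation p = 0.33, the smallest possible). RNA genes other than gcvB held 9.04 ± 1.65% and 9.17 ± 0.726% (SD, n = 2 each; exact permutation p = 1.0). The 10 most abundant genes of each library held 20.3 ± 3.06% in WT and 36.6 ± 3.88% in rpsAΔ56 (SD, n = 2 each; exact permutation p = 0.33). Ribosomal RNA held 0.562 ± 0.289% and 0.549 ± 0.172% (SD, n = 2 each; exact permutation p = 1.0). The cold shock gene cspA held 2.13 ± 1.2% and 6.53 ± 5.87%, and the transfer-messenger RNA ssrA 3.36 ± 0.777% and 3.21 ± 0.722% (SD, n = 2 each; exact permutation p = 0.667 for both), both chosen after their values were seen.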

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

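With 2 libraries per group, the edgeR test recovered 4-fold changes in 0 of 50 simulated cases, so smaller changes were below what it detects at this spread. The 19 calls became 18 with the replicate block, 19 with RLE, 20 with upper-quartile scaling, 18 at thinned depth and 22 in limma-voom, and among these cheY was the only named call lost, with the block. They became 177 in DESeq2, 361 with replicate block in DESeq2 and 0 at an adjusted p under 0.01, and ranged from 28 to 56 with 1 library left out, where the lone library is assumed to vary like the other group. The number of lists past the threshold, 14, became 7 to 14 with 1 library left out, 16 with the replicate block, 11 to 16 under the other scalings, filters and tools, and 0 with an estimated correlation and 0 in fry. The rpsA log2 fold change lay between -2.07 and -1.65 in the fits where it was recorded, which leaves out DESeq2 with the block. At -1.95 in DESeq2 without the block it passed the threshold (adjusted p = 0.0440). It did not pass in edgeR (adjusted p = 0.424, and 0.205 with the block). In the authors' table its adjusted p was 0.00641. Against the 352 calls of the authors' deposited table, the same counts gave 19 in edgeR, 18 with the replicate block and 177 in DESeq2. Directions turned for hupB (-3.74 to 0.77 with 1 library left out), the cold shock median (-0.37 to 1.39), ibsA (-0.71 to 3.70, and -0.22 in the single-end pair) and ibsD (-0.25 to 4.11). The cause was not tested for any of these. Scaling moved the median log2 fold change of all genes from 0.07 (TMM) to 0.02 (RLE) and 0.34 (upper quartile), and relative to it the flagella median lay between -3.45 and -3.38. Besides cheY, fliS, fliC and the lists for translation factors and RNA polymerase, the block changed no other call of a named gene or list in edgeR and camera. Corrections for GC content and gene length were not run.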

Other observations

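Outside the 31 lists, the authors' deposited table calls 185 genes, 99 higher and 86 lower in rpsAΔ56; the genes in this and the next paragraph were picked after their values were seen and tested for no enrichment. Of 7 leader peptide genes ahead of amino acid biosynthesis operons, 6 are called higher there, 0 lower, and trpL has no adjusted p. They are ivbL at 3.33 (adjusted p = 9.25e-10), ilvL at 3.03 (1.51e-06), hisL at 2.52 (8.69e-04), thrL at 2.73 (0.00215), pheL at 2.33 (0.00648) and leuL at 1.99 (0.0183), as log2 fold changes and adjusted p of the authors' table. For all but ivbL (3.79 and 3.63) the value was larger in the paired-end pair. Log2 fold changes in the single-end and paired-end pairs were 0.30 and 2.78 for trpL, 0.78 and 6.83 for thrL, 1.54 and 5.30 for pheL, 1.76 and 4.73 for hisL, 2.66 and 4.67 for ilvL, and 1.56 and 3.16 for leuL. In the edgeR fit made here 0 of the 7 passed (adjusted p from 0.254 for ivbL to 0.655 for leuL). The third gene of the glyoxylate shunt operon, aceK, stood at 3.08 in the authors' table (adjusted p = 5.74e-08), beside aceB and aceA of the TCA cycle list at 3.62 (9.03e-12) and 3.02 (6.29e-08), and it did not pass in edgeR (adjusted p = 0.0993).

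Among genes of sugar metabolism, rpiA at -2.68 (adjusted p = 2.94e-06), fbaA at -2.35 (6.59e-05), gapA at -1.80 (0.00432) and pykF at -1.78 (0.00664) were lower in the authors' table and rpiB at 1.82 (0.0154) was higher, while none of the 5 passed in edgeR (adjusted p 0.166 to 0.495). The main aerobic ribonucleotide reductase genes nrdA (-1.98, adjusted p = 0.00124) and nrdB (-1.78, 0.00561) were lower while nrdH (3.07, 4.39e-07), nrdI (2.12, 7.63e-04) and nrdE (2.09, 9.57e-04) of the alternative enzyme were higher, all in the authors' table. None of these passed in edgeR. Besides yhjH, flxA, ves and yjcZ, lower genes outside the lists in the authors' table included yhjG, next to yhjH, at -4.09 (5.42e-13), yghJ at -2.95 (2.77e-07) and yeeR, next to flu, at -3.05 (6.29e-08), and none of these 3 passed in edgeR (adjusted p 0.0730, 0.126 and 0.0968).

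Of the tests in the next 3 paragraphs, the comparison of small regulatory RNAs with transfer RNA genes was set before its result was seen, and the others after.

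The fall of flagellar genes was uneven: genes of the third tier, which need the sigma factor FliA (15 genes), had a median log2 fold change of -6.50, and second-tier genes of the hook and basal body (27 genes) -2.86. The difference was 3.63 (permutation over genes, p = 1e-05, the smallest 100000 resamples can give). Genes of the same operon share transcripts, so that p treats dependent genes as independent and measures no spread between libraries. The difference was 1.77 in the single-end and 3.92 in the paired-end pair. It argues against a minority of motile cells among cells with no flagellar transcripts, which would lower both tiers alike. A few genes taking most of the counts would lower all remaining genes alike, and with library totals as the only scaling the 4339 genes outside the list had a median of 0.027 against -3.32 (SD 1.87 across genes) for the list. Whether lower flhD and flhC levels may be the source cannot be told apart from other sources with these values: flhD stood at 1.56 (SE 0.997; -0.14 and 4.20 in the single-end and paired-end pairs) and flhC at -2.34 (SE 0.751), and flhC had 3.84 and 9.49 counts per flhD count in WT against 0.425 and 0.249 in the mutant. The S1 deletion itself, or a second change in the mutant strain, remains open and untested.

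Within the srl operon only srlA, weighed here because it was the only gene that rose in edgeR, passed that test, and the values ran from 7.59 for srlA (SE 0.884) to -0.18 for the last gene, srlQ. The genes flanking the operon are mltB, next to srlA, and norR, beyond srlQ at the other end. In the mutant libraries srlA stood 3.18 and 3.45 log2 units above the higher of these flanking genes in CPM per kb (SD of the 2 values 0.188). The flanking genes were taken by position and not by strand, so whether either could be transcribed into srlA was not examined. If one could, these levels would argue against read-through as the whole source, unless the flanking gene's part of such a transcript decays faster. The 94 carbon source genes outside srlA, srlE, srlB and srlD had a median of 0.98 (SD 1.22 across genes). Their highest value was 4.03 for malM (SE 1.32), against 5.82 for srlA minus 2 SE. A rise of the size typical of these genes would thus not reach that of srlA. Because srlA was picked for its rise, a shared rise of unequal size across genes is not excluded. Pairs differed further along the operon, with srlD at 2.18 in the single-end and 6.14 in the paired-end pair. The genotype stays open as an explanation, untested.

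The median rise of small regulatory RNAs was 2.50 log2 units higher in the paired-end than in the single-end pair. The median of transfer RNA genes, which are short too, minus that of small RNAs was -1.90 in the paired-end pair (median 0.95 of 85 genes against 2.85 of 39). Its permutation p over genes was 1e-05, the smallest 100000 resamples can give. That p treats genes as independent and measures no spread between libraries. In the single-end pair the difference was -1.16. The 2 values argue against recovery of short RNAs in general as the whole cause of the rise within a pair. They do not test the difference between pairs, which transfer RNA genes showed as well. The transfer RNA median was -0.82 in the single-end and 0.95 in the paired-end pair, against 0.34 and 2.85 for small RNAs. From the single-end to the paired-end library both classes stood lower in WT, with median shifts of -2.23 for transfer RNA genes and -1.53 for small RNAs. That goes with a recovery difference as a part of the difference between pairs. In rpsAΔ56 the 2 classes moved by -0.30 and 1.27. Protein-coding genes had medians of 0.03 and 0.04 in the single-end and paired-end pairs. With 1 library per strain and mode, sequencing mode, a difference of single libraries and the genotype stay open, all untested.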
